A study of Mus musculus with 24 samples.

How the data were processed

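The samples were mouse embryonic fibroblasts, primary connective tissue cells grown from day 13.5 embryos of crosses between C57BL6 mice carrying 1 working copy of the gene for CHIP. CHIP, encoded by Stub1, is a ubiquitin ligase that works with the HSP70 and HSP90 chaperones. Cultures with both copies of the gene (wildtype) or none (CHIP null) were kept at 37 °C or heated to 43 °C, and the labels give 30 or 240 min for each. Every combination had 3 arrays, 24 arrays in 8 groups. Group, time and replicate number were taken from the titles of the samples.

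Per the labels, 500 ng of total RNA per sample was amplified and labelled with Cy5, and each array also received a Cy3-labelled common reference, Universal Mouse Reference RNA, so no sample RNA was measured in Cy3 and no dyes were swapped. Per the file headers, the 44K Agilent oligonucleotide arrays were scanned on a GenePix 4000B scanner and quantified with Agilent Feature Extraction 9.1.3.1. The deposited spot intensity values are mean pixel values, and the local background intensity values are medians, both on a linear scale and not corrected, per the file headers. The same files hold a log10 ratio of Cy5 over Cy3 after background subtraction and linear and lowess dye normalization, per the file headers; it served as an alternative. Other deposited columns are flags for background, saturation and outlier pixels, per the file headers.

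The authors also deposited a value table of processed values for 28139 probes. Its scale, centring and direction were not stated and were found by setting each column against the scanner files. A control column equals the scanner files' log10 ratio divided by the natural log of 2, with at least 99.25% of probes within 0.001, and so runs in the direction Cy5 over Cy3. A heat shock column equals the same quantity minus the mean of the 3 controls of that genotype and time. Scale and direction are thus settled from the values, and why the ratio was divided by that constant is not given in the sources used here. All 24 columns matched, with a correlation of at least 0.9996, a scanner file of the same genotype, treatment and replicate number but of the other time label. The correlation with the scanner file of the same label was at most 0.9004. The column medians of the value table were 0, 0 and -0.01 for the wildtype control columns labelled 30 min, 0.00, 0.02 and 0.02 for the heated wildtype, 0.01, -0.01 and -0.00 for the CHIP null controls and -0.00, 0.02 and 0.02 for the heated CHIP null. In the columns labelled 240 min they were -0.01, -0.02 and -0.03, then -0.01, -0.00 and -0.01, then -0.03, -0.05 and -0.02, and last -0.01, 0.02 and 0.01 in the same order of groups. Which of the 2 time labels is right is not given in the sources used here, and all times in the text are those of the labels on the scanner files.

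Background was corrected with normexp at an offset of 50, and Cy5 over Cy3 ratios were normalized within each array by loess, with control spots at weight 0. That offset is large against the median Cy5 signal over background, 4.83 to 10.5 depending on the array. It draws the ratios of dim probes towards 0. Folds and counts above a fold threshold are those of the offset ratios and may understate the folds of RNA. The value of a probe is the log2 of Cy5 over Cy3, so that a difference between groups is a difference of sample RNA relative to the common reference. Control spots and 333 spots marked as outliers were left out; 43379 spots that are not controls held 41174 probes. Spots of a probe were averaged. Probe names were brought up to date through a reference table of RefSeq genes (assembly GRCm38.p6; the build of the array design is not given in the sources used here), by accession for 22951 probes, by symbol for 6659 and by synonym for 3109, and 8455 kept the name in the file. Each gene or feature was represented by its probe of highest mean brightness, which left 27670. A gene was tested if its probe was well above background in Cy5 on all 3 arrays of at least 1 group, and this held for 19368 probes and 13488 genes or features, after 10 were left out for a group without any value. Loess assumes that most genes do not change or change evenly in both directions, so a general loss or gain of mRNA cannot be seen.

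Tests used limma 3.58.1 in R 4.3.3 with the packages statmod 1.5.0 and data.table, version 1.17.8. A linear model with a mean for each of the 8 groups was fitted to all 24 arrays with empirical Bayes moderation, which gave 16 residual and 11.7 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method per comparison at 0.05. The comparisons were the heat shock effect in each genotype and time, the genotype effect in each treatment and time, the time effect in the controls of each genotype, and the differences between heat shock effects by genotype and by time. A named change is a log2 change with its standard error from this fit, over 3 arrays in each group. Of 34 gene lists written beforehand, 33 with 5 or more measured genes were tested with camera at its preset correlation of 0.01 on the 13373 genes complete on all arrays, and the p-values were adjusted over all lists and contrasts of a family. An adjusted p "with an estimated correlation" comes from camera with the correlation between the genes of the list estimated from the residuals. Counts of list members were made over all genes tested and, where given, adjusted over the list alone.

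Genes were named by a fixed rule: 9 genes of the study's question in every contrast, of which Hspa1b was not measured here; up to 8 of the highest and 8 of the lowest changes per contrast among genes called, measured on all arrays of the contrast and without overlap between the groups; up to 4 called members per list; and up to 4 genes seen in only 1 of the groups compared. For the last kind the fold is a lower bound: the mean of the group well above background against the mean, in the other group, of the higher of the probe's own signal and the lowest signal of any probe well above background on that array, both as normalized Cy5 values, which stays open to dye bias. Where the fold of the ratios was lower, that fold is given instead. Where several probes measured a named gene and disagreed, the others are given. Some genes that the rule selects are not reported here.

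The groups, the tests, the gene lists, the naming rule and most alternatives were set before the data were examined. The alternatives were the Feature Extraction ratio, the value table, an offset of 10, median centring in place of loess, quantile scaling between arrays of the mean brightness, the Cy5 channel alone, other filters on dim probes, every probe on its own, a fit to only the groups compared, array weights, slide or replicate number as a block, fry in place of camera, and leaving out each array in turn. Outlier spots kept, ratios scaled to a common slope, and heat shock compared within the slide that holds both groups were chosen after seeing the data.

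As a check, the fit was tested on simulated ratios of 13373 genes, with 67, 67 and 66 changed 1.2-, 1.5- and 2-fold. At 2-fold, 98.5% to 100% were recovered per contrast. At 1.5-fold it was 97% to 100%, or 83.6% to 89.6% for differences between heat shock effects. At 1.2-fold, 44.8% to 62.7% were recovered, or 8.96% to 23.9% for those differences. All 5 lists shifted by 1.2-fold were found in every contrast, with 1 false list call in the heat shock effect of the wildtype at 240 min and 0 in the others. The simulated genes varied independently and the lists were random. The check does not cover correlation between genes, slide effects or contrasts with more changed genes. False list calls may be more frequent in the data.

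Depth on an array is signal over background. Between 33.7% and 49.6% of probes were well above background in Cy5 and 49.9% to 62.6% in Cy3, and at most 1 Cy5 spot per array was saturated. Precision is limited by the number of arrays, 3 per group; the median standard error of a log2 change between groups was 0.07. The labels call the samples of a condition biological replicates but do not say whether they came from separate embryos or cultures, so p-values measure the spread between these arrays. The arrays were printed 4 to a slide, and no slide held both genotypes under the same treatment. Each time label was scanned as its own set, so time and scan set cannot be told apart. Whether the replicate numbers pair samples across groups is tested in the closing section.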

Results

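RNA from mouse embryonic fibroblasts was measured on 24 arrays, each comparing a sample labelled with Cy5 with a common reference RNA labelled with Cy3. The design crossed genotype (wildtype or CHIP null), temperature (37 or 43 °C) and time (30 or 240 min), with 3 arrays in each of the 8 groups. It asks how loss of CHIP, a ubiquitin ligase that acts with heat shock chaperones, alters the transcriptional response to heat, with the p53 programme of cell death and the protein DAXX named in the title. In Cy5, 40.7% ± 2.7 (SD, n = 3) of probes were well above background in the wildtype controls labelled 30 min and 37.9% ± 1.9 after heat. The corresponding values of the CHIP null were 41.4% ± 1.4 and 35.4% ± 1.8. On arrays labelled 240 min they were 48.6% ± 1 and 46% ± 0.4 in the wildtype and 48.5% ± 1.1 and 45.4% ± 0.41 in the CHIP null. Replicate arrays of a group correlated at 0.981 to 0.995 across probes, and 0 pairs were identical. The authors' value table matched the scanner files of the other time label in all 24 columns. Therefore "30 min" and "240 min" below are the labels of the scanner files, and the comparisons between times carry that uncertainty and also compare separate scan sets.

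Stub1, the gene that encodes CHIP, was checked first in every sample. Its log2 ratio to the reference lay between -0.24 and -0.01 on the 12 wildtype arrays and between -2.43 and -1.72 on the 12 CHIP null arrays. The CHIP null controls were lower by a log2 difference of -1.83 (SE 0.07, n = 3 against 3) at 30 min and -2.08 at 240 min, and the heated cells by -1.74 and -2.02. Heat changed Stub1 by 0.15 (adjusted p = 0.16) and 0.12 in the wildtype, which did not pass the test. In the CHIP null it rose by 0.24 at 30 min, or -0.16 with median centring, where the median of all genes was -0.18, and the 0.18 at 240 min did not pass.

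**Figure D1:**
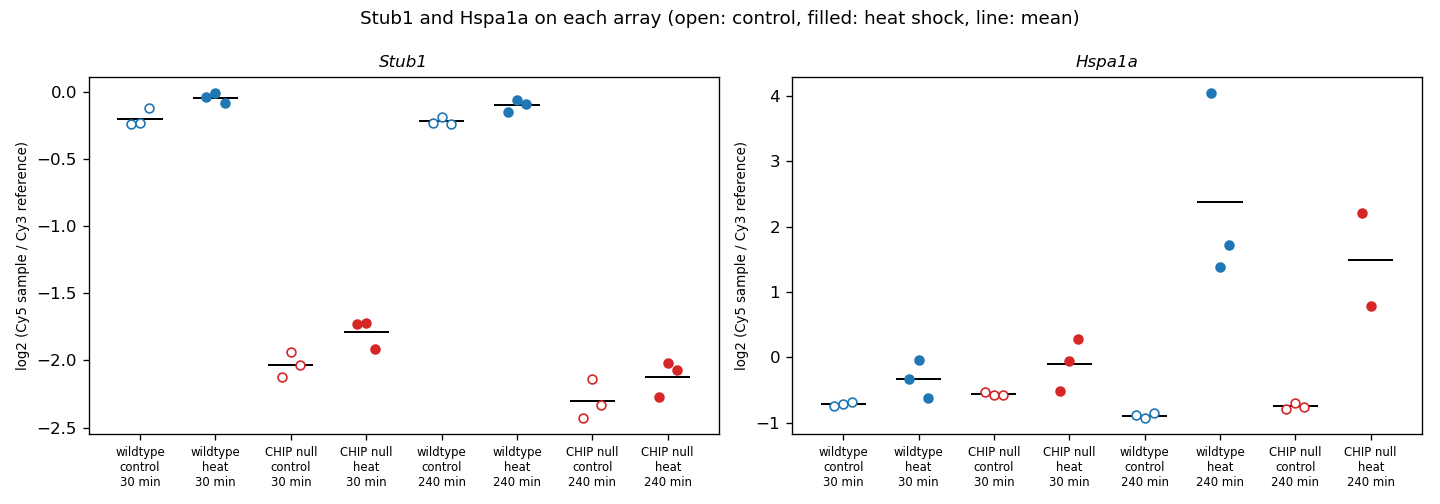
Log2 ratio to the common reference (vertical axes) of Stub1 and Hspa1a on each array (points) by group, with a line at the mean of the group; the wildtype is blue and the CHIP null red, and open points are controls. Stub1 lies between -2.43 and -1.72 on the CHIP null arrays and between -0.24 and -0.01 on the wildtype arrays, and Hspa1a reaches 4.04 on a heated wildtype array labelled 240 min.

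Sex-linked transcripts differed between the cultures labelled 30 min. Xist, the RNA that coats the inactive X chromosome of female cells, was at least 3.48-fold higher in the CHIP null controls (log2 1.80 ± 0.11, SE) and at least 3.06-fold higher in its heated cells (1.64), since the wildtype side was not well above background. Its other probes gave 0.09 to 0.79. Eif2s3y and Ddx3y, genes of the Y chromosome, were lower in the CHIP null controls by at least 2.56-fold (-1.36) and 1.97-fold (-0.98), and in the heated cells by at least 1.96-fold (-0.97) and 1.72-fold (-0.78). On arrays labelled 240 min these Y-linked transcripts were not well above background on any array, and Xist lay between -1.99 and -1.58 on every array of that set. Only 3 sex-linked transcripts were measured, so their list was not tested. The genotype comparisons at 30 min below therefore also compare cultures that differ in Xist and Y-linked RNA.

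In the wildtype at 30 min, heat changed 1964 of 13488 genes, 913 higher and 1051 lower, by limma at an adjusted p of 0.05. Only 45 changed more than 1.5-fold. The RNA component of the mitochondrial RNA processing endoribonuclease, Rmrp, rose 3.85-fold (log2 1.95 ± 0.13), and Dusp26, a protein phosphatase, rose by 0.55 ± 0.08. The complement receptor C5ar2, not well above background in the controls, was at least 3.35-fold higher. Several of the larger falls were among genes of macrophages: the lysozymes Lyz2 (-2.09 ± 0.08, though -0.26 by its other probe) and Lyz1 (-1.50), the scavenger receptor Marco (-1.58 ± 0.08, 2.99-fold), the surface protease Adam8 (-1.30 ± 0.06) and the lysosomal protease Ctss (-0.79 ± 0.06). Nucks1, a nuclear phosphoprotein, and Rlim, a ubiquitin ligase, fell by 0.80 and 0.78, but their other probes changed by -0.11 to 0.06 and -0.13 to -0.10. In each gene named here from the extremes of a comparison between groups of arrays, all 3 arrays of one group lay beyond all 3 of the other.

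At 240 min 4245 genes changed in the heated wildtype, 2530 higher and 1715 lower, 168 of them more than 1.5-fold. Hspa1a, the inducible HSP70 chaperone, rose 9.66-fold (3.27 ± 0.38, adjusted p = 8.6e-07), with 1.43 to 3.08 by its other probes. The heated replicates spread widely, at log2 ratios of 4.04, 1.39 and 1.72 against -0.89, -0.93 and -0.85 in controls. Rmrp rose 5.13-fold and Dusp26 by 0.62, and C5ar2 was at least 1.78-fold higher. Falls included the kinase Taok1 (-1.12 ± 0.11, other probes -0.56 to -0.39), the motor protein Kif5b (-1.04 ± 0.12, other probe -0.42), the ADP-ribosylating enzyme Tnks2 (-1.02, other probe -0.16), Nucks1 (-1.02) and Rlim (-0.94).

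In the CHIP null at 30 min, heat changed 4753 genes, 3052 higher and 1701 lower, 121 of them more than 1.5-fold. Rmrp rose 4.07-fold, Dusp26 by 0.89, and the cell cycle inhibitor Cdkn1c by 0.71 ± 0.09; C5ar2 was at least 3.08-fold higher. The mitochondrial chaperonin Hspd1 fell by 0.99 ± 0.12 (other probe -0.55), Nucks1 by 1.13, Rlim by 1.03 and Tnks2 by 0.89. Lyz2 fell by 0.89 (other probe 0.11). At 240 min 5263 genes changed, 3301 higher and 1962 lower, 238 of them more than 1.5-fold. Rmrp rose 6.01-fold, and Hspa1a by 2.24 ± 0.42 (other probes 1.66 to 2.97), with 2.21 and 0.78 on the 2 heated arrays with a value against -0.79, -0.70 and -0.76 in controls. Heated replicate 1, without a value, was highest by the other probes (2.2 to 3.9). Dusp26 rose by 0.79 and C5ar2 at least 2.06-fold. Taok1 (-1.14), Kif5b (-1.10), Tnks2 (-1.06), Rlim (-1.06) and Nucks1 (-1.04) fell as in the wildtype.

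These counts and splits depend on scaling, slide and single arrays. Without 1 array at a time the wildtype had 1052 to 2000 calls at 30 min and 2681 to 4268 at 240 min, and the CHIP null 3580 to 4495 and 3062 to 6152. With slide as a block the calls in the wildtype were 449 at 30 min and 616 at 240 min, and in the CHIP null 2675 and 2742. Every slide that holds both treatments of a genotype has only 1 array of one of them, a control in the wildtype at 30 min and the CHIP null at 240 min and a heated array otherwise, against 3 of the other. The slides are linked in a chain, so the block gives the same changes as the comparison within those slides (449, 616, 2679 and 2742 calls) and is no second check. Every heat and genotype value with slide as a block therefore rests on such a lone array, which is assumed to vary like the others. It shows how far a result depends on slide or on that array, without telling these apart, and gives a call no separate support. Median centring moved the median change of all genes to -0.09 and -0.03 in the wildtype at 30 and 240 min and to -0.18 at both times in the CHIP null, against 0.01, 0.06, 0.03 and 0.07 with loess. List values below are therefore relative to the median of all genes. The share of calls that were higher was 46.5%, 59.6%, 64.2% and 62.7% in that order, but 4.2%, 4.3%, 0.8% and 0.4% with median centring and 39.3%, 44%, 46% and 41.7% with the Feature Extraction ratio. Probe choice mattered for falls: of genes that fell more than 1.5-fold and had another probe, that probe was also called lower in 7 of 20, 68 of 121, 29 of 64 and 100 of 166. It had the same sign in 17, 101, 53 and 146 and was dimmer, with a median log2 intensity of 6.72 against 9.64 in the wildtype at 30 min. The rise of Rmrp with slide as a block was 1.89, 2.47, 1.88 and 2.70, and that of Hspa1a 4.93 and 2.26 at 240 min, the former from the heated array at 4.04 alone; the fall of Hspd1 in the wildtype at 240 min (-0.51, adjusted p = 0.059) then lost its call. The heat effects of both genotypes correlated across genes at 0.744 at 30 min and 0.888 at 240 min. At 240 min 1683 genes were higher in both and 1445 lower in both, where independent lists would share 619.2 and 249.5, and 0 were called in opposite directions.

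Among 31 cytosolic heat shock proteins and co-chaperones, the calls went both ways in each heat comparison. At 30 min 3 rose and 9 fell in the wildtype (adjusted over the list alone, 5 and 10) and 7 rose and 10 fell in the CHIP null. At 240 min 4 rose and 5 fell in the wildtype and 5 rose and 5 fell in the CHIP null. The list as a whole was not called, with adjusted p of 0.11, 0.73, 0.07 and 0.27 for the wildtype at 30 and 240 min and the CHIP null at 30 and 240 min. Besides Hspa1a, the small heat shock protein Hspb1 rose by 0.31 and Cryab by 0.29 in the wildtype at 240 min. Hspd1 fell in all 4 comparisons, by -0.64, -0.81, -0.99 and -0.83. Hspa8, the constitutive HSP70, rose by 0.25 only in the CHIP null at 30 min, which was -0.10 with median centring, against -0.18 for the median of all genes, and 0.01 with slide as a block. Hsf1, the main heat shock transcription factor, was not called in any (0.14, 0.09, 0.11 and 0.03). With median centring it was called lower in the CHIP null at 30 min (-0.35, limma adjusted p = 0.014), below that median of -0.18.

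Genes of mitosis fell after heat on the arrays labelled 30 min. In the wildtype 17 of 23 fell and 0 rose (19 adjusted over the list alone), with a list median of -0.24 relative to all genes and an adjusted p of 9.4e-16, or adjusted p = 0.00096 with an estimated correlation. In the CHIP null 13 fell (14 over the list alone), with a median of -0.21 and an adjusted p of 1.9e-07, or adjusted p = 0.022 with an estimated correlation. The centromere motor Cenpe fell by 0.85 and 0.86, although by -0.19 to -0.16 in the wildtype by its other probes, the spindle midzone protein Prc1 by 0.67 ± 0.06 and 0.57, and the proliferation antigen Mki67 by 0.64 in the wildtype. With slide as a block, 1 array against 3, the adjusted p was 7.5e-12 and 4.1e-05 and the list medians were -0.23 and -0.21. At 240 min 3 rose and 7 fell in the wildtype and 5 rose and 6 fell in the CHIP null, with no list call (adjusted p = 0.29 and 0.37).

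Immediate early genes, the rapidly induced growth response genes, fell on the arrays labelled 240 min. In the wildtype 13 of 29 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.21, an adjusted p of 1.1e-06 and, with an estimated correlation, an adjusted p of 0.024. In the CHIP null 17 fell (18 over the list alone), with a median of -0.34 and adjusted p of 4.1e-08 and, with an estimated correlation, 0.018. Dusp6, an ERK phosphatase, fell by 0.66 ± 0.08 and 0.74, the transcription factor Klf4 by 0.59 and 0.68, and the matricellular protein Ccn1 by 0.57 and 0.60. Blocking by slide, 1 array against 3, gave adjusted p of 2.9e-05 and 4.2e-08 and list medians of -0.15 and -0.35. At 30 min 10 fell and 1 rose in the CHIP null (adjusted p = 0.0039), a call lost with an estimated correlation (adjusted p = 0.28) and with slide as a block (adjusted p = 0.057). The wildtype list was not called at 30 min (adjusted p = 0.15).

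Targets of p53 did not rise as a group after heat. Of 18 targets in apoptosis, 1 rose and 3 fell in the wildtype at 30 min, 3 and 4 at 240 min, and in the CHIP null 4 and 4 and then 4 and 5, with no list call in any (adjusted p = 0.19, 0.27, 0.31 and 0.31). Pmaip1, the cell death protein NOXA, fell by 0.66, 0.32, 0.70 and 0.52 in the order of wildtype and then CHIP null at 30 and 240 min, but by 0.17 (adjusted p = 0.47) in the wildtype at 240 min with slide as a block. Zmat3, which encodes an RNA-binding protein induced by p53, fell by 0.55, 0.71, 0.67 and 0.63. Of 20 targets in arrest, repair and feedback, 4 fell and 0 rose in the wildtype at 30 min (6 and 1 over the list alone; adjusted p = 0.042, and adjusted p = 0.30 with an estimated correlation). The list was not called in the other comparisons. Mdm2, the ubiquitin ligase of p53, fell by 0.37, 0.58, 0.47 and 0.54, and its other probe gave -0.10 to -0.27; with slide as a block the wildtype falls did not pass (adjusted p = 0.15 and 0.075). Cdkn1a, the p53-induced cell cycle inhibitor p21, rose by 0.25 and 0.22 in the CHIP null, and Trp53 itself rose there by 0.25 and 0.18. With median centring these were -0.16, -0.12, -0.018 and -0.12, all above the median of all genes (-0.18 at both times). Both Trp53 (0.16 and 0.10) and Cdkn1a at 240 min (0.23, adjusted p = 0.098) lost these calls with slide as a block.

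Daxx, the apoptosis and chromatin regulator named in the title, was not called in any heat comparison (-0.15, -0.10, 0.01 and -0.04) or genotype comparison (-0.09, -0.11, 0.06 and -0.06). With median centring it was called lower in the heated CHIP null at 30 min (-0.41, limma adjusted p = 0.0093), where the median of all genes was -0.18. Of 20 genes of the DAXX, HIPK and ASK1-JNK pathway, 5, 8, 7 and 8 fell and 0, 2, 2 and 3 rose in the same order of heat comparisons (over the list alone 9, 8, 7 and 9 fell). The adjusted p was 0.00044, 0.026, 0.019 and 0.018, and each call was lost with an estimated correlation (adjusted p = 0.21, 0.49, 0.44 and 0.44). Blocking by slide, 1 array against 3, gave 0.00031, 0.11, 0.0023 and 0.0034 and list medians of -0.17, -0.073, -0.15 and -0.20. The kinase Hipk3 fell by 0.64, 0.92, 0.85 and 0.96 and Hipk2 by 0.65, 0.79, 0.77 and 0.95. The other probe of Hipk3 gave -0.39 to -0.01 and that of Hipk2 0.03 to 0.09. In the list of 20 BCL2 family and caspase genes, 3 fell and 1 rose in the wildtype at 240 min (adjusted p = 0.037; adjusted p = 0.44 with an estimated correlation), and the other comparisons gave no call.

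Ribosomal protein genes were higher after heat. Of 45, the numbers that rose were 29 and 16 in the wildtype at 30 and 240 min and 41 and 12 in the CHIP null, with 0 falling (33, 21, 43 and 6 over the list alone). The list medians were 0.23, 0.10, 0.32 and 0.06 and the adjusted p 2.1e-14, 0.0022, 1.1e-13 and 0.036, but no call held with an estimated correlation (adjusted p = 0.29, 0.54, 0.30 and 0.61). At 240 min the medians turned to -0.01 and -0.04 with a normexp offset of 10. The adjusted p with slide as a block, 1 array against 3, was 5.2e-08, 0.025, 1.2e-12 and 0.24, and the medians were 0.19, 0.10, 0.35 and 0.031. Rps27, a protein of the small subunit, rose by 0.46 and 0.58 at 30 min, the wildtype value losing its call with slide as a block (0.41, adjusted p = 0.060). Among 23 replication-dependent histones 7 rose in the wildtype at 30 min (11 over the list alone; adjusted p = 0.0024, and adjusted p = 0.49 with an estimated correlation) and 9 in the CHIP null, where the list was not called (adjusted p = 0.070).

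Macrophage markers fell with heat in 1 comparison and rose in 2 others. In the wildtype at 30 min 9 of 13 fell (10 over the list alone), with a median of -0.30 and an adjusted p of 2.1e-14, or adjusted p = 0.025 with an estimated correlation. Blocking by slide, 1 control against 3 heated arrays, gave an adjusted p of 1.6e-14 and a median of -0.39. At 240 min 5 rose in the wildtype (adjusted p = 0.032) and 10 in the CHIP null (adjusted p = 0.0038), calls lost with an estimated correlation (adjusted p = 0.53 for both). Markers of other cell types were higher in the heated CHIP null at 30 min, with 6 of 9 endothelial, 10 of 15 neuronal and glial, 9 of 19 muscle, 5 of 6 adipocyte and 4 of 5 erythroid markers up and 1 muscle marker down. Their list medians were 0.28, 0.23, 0.26, 0.27 and 0.39 and their adjusted p 0.0054, 0.0022, 0.011, 0.019 and 0.019, none of which held with an estimated correlation (adjusted p = 0.49, 0.44, 0.53, 0.53 and 0.53). After the ratios of each array were scaled to a common slope, a setting chosen after seeing the data, the adjusted p was 0.071, 0.052, 0.53, 0.75 and 0.92. In the wildtype at 30 min the endothelial list was called with 2 members up and the muscle list with 0 (adjusted p = 0.041 and 0.026, then 0.53 and 0.57 with an estimated correlation). At 240 min 6 endothelial, 7 of 11 epithelial and 6 neuronal markers rose in the heated CHIP null (adjusted p = 0.032, 0.024 and 0.032, and adjusted p = 0.53 with an estimated correlation for each).

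**Figure D2:**
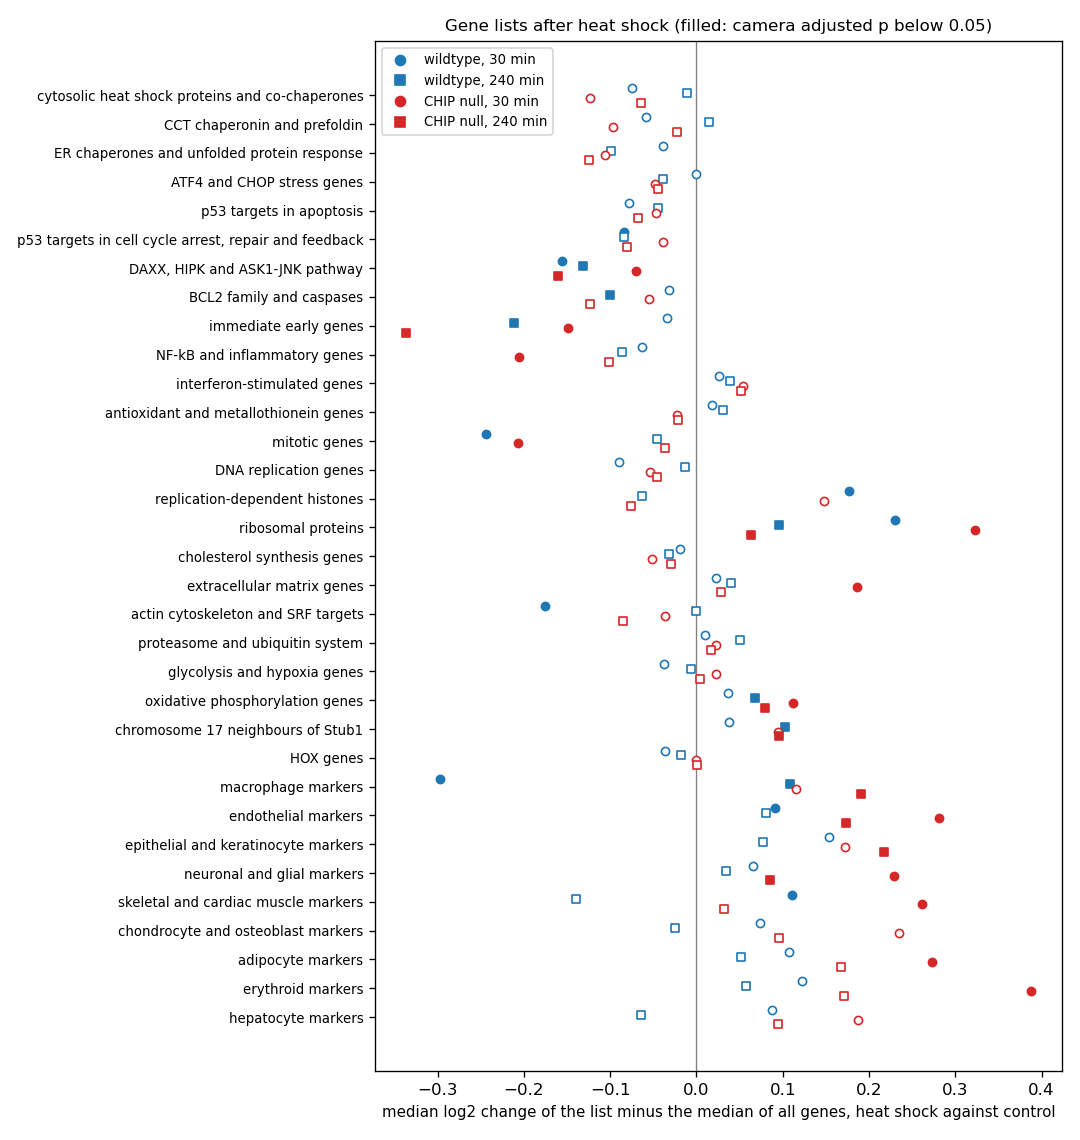
Median log2 change after heat of each of 33 gene lists minus the median of all genes (horizontal axis) in the 4 heat comparisons; circles are arrays labelled 30 min and squares 240 min, blue the wildtype and red the CHIP null, and filled symbols have a camera adjusted p below 0.05. Mitotic genes lie at -0.24 and -0.21 at 30 min, immediate early genes at -0.21 and -0.34 at 240 min, and macrophage markers at -0.30 in the wildtype at 30 min.

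Smaller list changes after heat were called in 1 to 3 comparisons each and all lost with an estimated correlation. Of 16 actin and SRF target genes 6 fell in the wildtype at 30 min (9 fell and 1 rose over the list alone; adjusted p = 0.020, then 0.44). Of 28 extracellular matrix genes 16 rose in the CHIP null at 30 min, the proteoglycan Dcn by 0.48, with 0 falling (adjusted p = 0.021, then 0.53), and the list median turned to -0.0010 with median centring. There 7 of 17 NF-kB and inflammatory genes fell and 2 rose (adjusted p = 0.019, then 0.54), among them the chemokines Cxcl5 (-0.78) and Ccl7 (-0.76). Of 27 oxidative phosphorylation genes 11 rose and 1 fell in the CHIP null at 30 min (adjusted p = 0.017, then 0.53), with the median turning negative with the Feature Extraction ratio, an offset of 10, median centring and a common slope. It was also called at 240 min, with 7 up in the wildtype (adjusted p = 0.036) and 10 up and 1 down in the CHIP null (adjusted p = 0.032). Among 21 neighbours of Stub1 on chromosome 17, 10 rose in the wildtype and 9 in the CHIP null at 240 min (adjusted p = 0.016 and 0.032, then 0.53 for both). The lists of CCT chaperonin, ER chaperones, ATF4 and CHOP stress genes, interferon-stimulated genes, antioxidant genes, DNA replication, cholesterol synthesis, proteasome, glycolysis, HOX genes, chondrocyte and hepatocyte markers had adjusted p between 0.06 and 0.98 in the 4 heat comparisons. Hmgcs1, an early enzyme of cholesterol synthesis, nevertheless fell by 0.41, 0.82, 0.57 and 0.76, with -0.03, -0.14, -0.09 and -0.23 by its other probe.

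The genotype difference of the heat effect was called in 60 genes at 30 min, 52 higher in the CHIP null and 8 lower. The count ran from 16 to 232 when single arrays were left out, and 5 of 100 splits gave at least the 59 called among genes measured on all arrays, so chance is not excluded. Most of the named ones belong to macrophages: Marco by 1.83 ± 0.11, Lyz1 by 1.38, Lyz2 by 1.19 (0.37 by its other probe), Adam8 by 1.11 ± 0.09, the surface marker Adgre1 by 0.83 and Ctss by 0.77. Each was already lower in the CHIP null than in the wildtype controls. With heat, the mean log2 ratio of Marco went from 0.42 to -1.16 in the wildtype and from -1.95 to -1.695 in the CHIP null. That of Lyz1 went from -0.41 to -1.92 and from -2.49 to -2.62. For these genes the difference of the heat effect cannot be told apart from that of the controls. Of 13 macrophage markers 8 differed (13 over the list alone; adjusted p = 1.9e-26, or 0.0011 with an estimated correlation, and 3.5e-16 with slide as a block). Egr1, an immediate early transcription factor, was lower by -0.45, which was -0.22 (adjusted p = 0.44) with slide as a block. The block by slide left 10 genes called, with Marco at 1.68, Lyz1 at 1.37 and Adam8 at 1.03; median centring gave 5 and the fit to only these groups 17. At 240 min limma called 0 genes (471 at an unadjusted p under 0.05). The heat effect on Hspa1a differed by -1.03 ± 0.57 (adjusted p = 1.0) without heated CHIP null replicate 1. Its other probes, which include that array, gave -0.11 to 0.23. The main probe blocked by slide gave -2.67, from 1 heated wildtype array and 1 CHIP null control against 3 and 2 arrays. Median centring moved the median difference of all genes to -0.11 at 30 min and -0.17 at 240 min. The p53 target lists had adjusted p of 0.96 and 0.49 at 30 min and 0.90 and 0.73 at 240 min for this difference.

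Between genotypes, 4592 genes differed in the controls labelled 30 min, 1979 higher and 2613 lower in the CHIP null, 500 of them more than 1.5-fold, and 3706 in the heated cells, 1918 higher and 1788 lower, 408 more than 1.5-fold. Higher in the CHIP null were Mmp3, a matrix protease (2.52 ± 0.13 in controls and 2.50 in heated cells, 5.75-fold in controls), Il1rl1, the interleukin-33 receptor (2.49 and 2.28, other probes 0.35 to 0.97) and the protease inhibitor Slpi (2.22 and 2.31). The chemokines Ccl2 and Ccl7 (1.48 each) were higher in controls, and Cxcl5 at least 5.17-fold higher there. Lower were genes of neural cells: the proteoglycan Ncan (-3.62 ± 0.07 and -3.60), the brain fatty acid binding protein Fabp7 (-3.26 and -3.22) and the astrocyte membrane protein Mlc1 (-2.61 and -2.68). Marco (-2.36), Lyz2 (-2.69, other probe -0.42) and Lyz1 (-2.08) were lower in controls. All 13 macrophage markers were lower in the CHIP null controls (adjusted p = 2.4e-11, or 0.026 with an estimated correlation) and 3 in the heated cells (adjusted p = 0.045, then 0.54). Of the neuronal and glial markers 10 of 15 were lower in controls and 4 in heated cells (adjusted p = 3.4e-05 and 0.011, then 0.12 and 0.37). Fewer genes, 1631 and 1708, were called with slide as a block; Ncan was then at -3.51 and -3.63 and Mmp3 at 2.02 and 2.22. The median centring split was 66.8% higher in controls and 29% in heated cells, against 43.1% and 51.8% with loess.

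**Figure D3:**
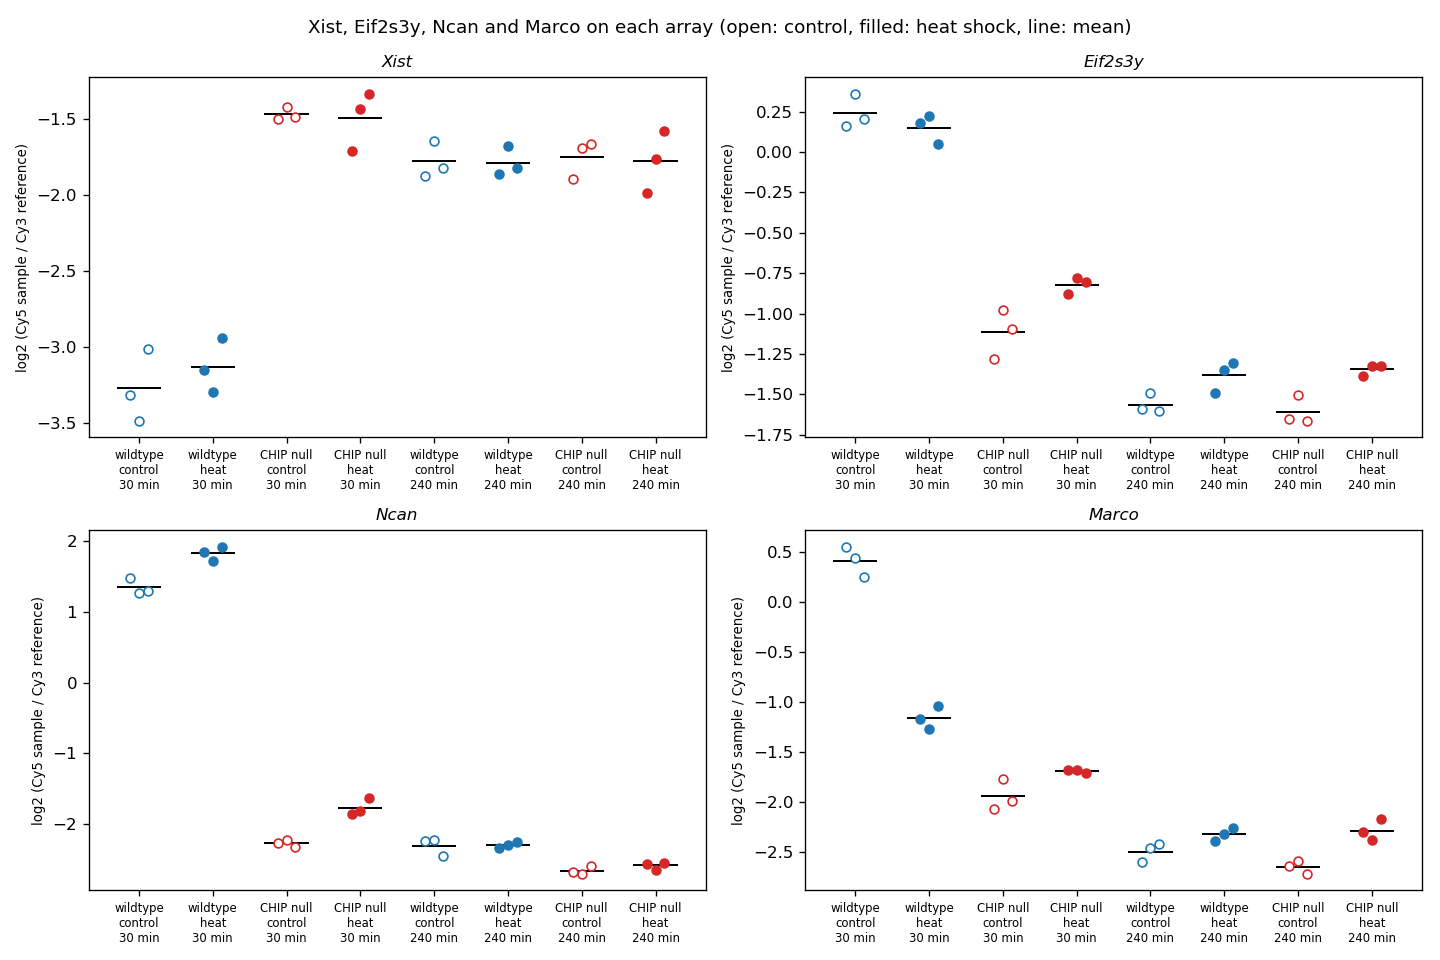
Log2 ratio to the common reference (vertical axes) of Xist, Eif2s3y, Ncan and Marco on each array (points), with a line at the mean of each group of 3; blue is the wildtype, red the CHIP null, open points are controls and filled points heated cells. Ncan lies between 1.27 and 1.93 on wildtype arrays labelled 30 min and between -2.71 and -1.63 on all others.

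Cell cycle and metabolic genes also differed at 30 min. Of 23 mitotic genes 21 were higher in the CHIP null controls and 22 in the heated cells, with medians of 0.67 in both (adjusted p = 1.8e-20 and 1.5e-23, or 8.4e-05 and 4.4e-05 with an estimated correlation). The spindle motor Kif20a was higher by 0.92 and 1.01 and Birc5 (survivin) by 0.86 and 1.10. Of 23 DNA replication genes 20 were higher in each (adjusted p = 1.7e-13, or 0.0013 with an estimated correlation), and 18 of 22 cholesterol synthesis genes (adjusted p = 2.8e-10 and 5.7e-10, or 0.00039 and 0.0004). Antioxidant and metallothionein genes were lower, 10 of 19 in controls with 1 higher and 12 in heated cells (adjusted p = 9.1e-05 and 1.4e-07, or 0.0052 and 0.0007), among them Mt2 (-1.15 and -1.26) and Hmox1, heme oxygenase (-0.95 and -0.94). The small heat shock proteins Cryab (-1.68 and -1.58, other probe -0.40 and -0.29) and Hspb8 (-1.32 and -1.26) were lower. The cytosolic heat shock list was not called (adjusted p = 0.59 and 0.10). At 30 min the sex-linked, macrophage and neural transcripts above differed between the same arrays.

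On the arrays labelled 240 min 1762 genes differed between the control genotypes, 648 higher and 1114 lower in the CHIP null, and 1749 between the heated ones, 629 higher and 1120 lower, with 185 and 145 more than 1.5-fold. Plac8 (1.43 in controls and 1.36 in heated cells), the matricellular protein Ccn5 (1.30 and 1.2) and the collagen receptor Itga11 (0.94 and 0.94) were higher. Lower were the opioid precursor Penk (-1.93 and -1.62, other probe -0.78 and -0.45), the mesothelial surface protein Msln (-1.67 and -1.56), the interferon-induced Bst2 (-1.55 and -1.50) and Isg15 (-1.38 and -1.45), the p53 target Perp (-1.50 and -1.46), the atrial myosin light chain Myl7 (-1.42 and -1.36) and the simple epithelial keratin Krt18 (-1.20 and -1.23). Interferon-stimulated genes were lower as a group, 14 of 20 with 1 higher in controls and 11 with 2 higher in heated cells (adjusted p = 3.5e-12 and 1.7e-09, or 0.0012 and 0.0035 with an estimated correlation). Extracellular matrix genes were higher, 17 of 28 in each with 3 and 4 lower (adjusted p = 3.5e-07 and 7.4e-08, or 0.035 and 0.026), with the proteoglycans Lum (-1.19 and -0.80) and Dcn (-1.04 and -0.87) among the exceptions. Actin and SRF targets were higher in controls, 7 of 16 (adjusted p = 3.1e-06, or 0.017), the smooth muscle calponin Cnn1 by 0.69, and 3 in heated cells (adjusted p = 0.0022, then 0.12). In the same arrays 9 and 7 macrophage markers (adjusted p = 4.5e-11 and 3.2e-08, or 0.026 and 0.061 with an estimated correlation), 13 and 9 neuronal and glial markers with 2 higher in each (5.8e-08 and 0.00055, or 0.037 and 0.20), 11 and 10 of 19 muscle markers with 1 higher in heated cells (1e-11 and 1.8e-06, or 0.07 and 0.22) and 6 and 4 of 11 epithelial markers (1.6e-05 and 0.010, or 0.17 and 0.45) were lower. The counts with slide as a block were 467 and 368, with Stub1 called at -2.14 and -2.0; Isg15 was then at -1.73 and -1.62 and Plac8 at 1.38 and 1.28. The share of calls that were higher in the heated cells was 36%, and 8.1% with median centring, which moved the median of all genes there to -0.13.

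Both targets of p53 and amino acid stress genes differed between the genotypes at both times. Of 18 p53 targets in apoptosis, 9 and 8 were lower in the CHIP null controls at 30 and 240 min with 1 and 2 higher, and 8 and 7 in heated cells with 2 and 1 higher (adjusted p = 0.0071, 0.00072, 0.0011 and 0.00056). With an estimated correlation the adjusted p was 0.11, 0.041, 0.049 and 0.037. Pmaip1 was lower by -1.42 and -0.39 in controls and -1.47 and -0.58 in heated cells, and its values at 240 min lost their calls with slide as a block (-0.18 and -0.56). Of 20 p53 targets in arrest, repair and feedback 11 and 5 were lower in controls and 9 and 5 in heated cells, with 0 higher (adjusted p = 0.00024, 0.049, 0.00033 and 0.020, or 0.0093, 0.17, 0.010 and 0.094 with an estimated correlation). Blocked by slide, the controls at 240 min had 0.24. Cdkn1a was lower by -0.58, -0.43, -0.53 and -0.36, of which both values in heated cells lost their calls with slide as a block (-0.35 and -0.36). Mdm2 was lower by -0.43 and -0.53 at 30 min (other probe -0.12 and -0.21), the former not passing with slide as a block (adjusted p = 0.088). Trp53 was higher only in the heated cells at 30 min (0.21, adjusted p = 0.011), and its other probe gave 0.38 there and 0.24 in the controls at 30 min, where the main probe gave -0.01. Of 21 ATF4 and CHOP stress genes 12, 13, 11 and 12 were higher in the same order, with 3, 0, 2 and 0 lower (adjusted p = 0.00067, 3.9e-12, 0.0017 and 1.4e-12, or 0.0086, 4.4e-05, 0.012 and 4.4e-05). Trib3, a stress-induced pseudokinase, was higher by 0.54 and 0.67 at 240 min, Asns, asparagine synthetase, by 0.50 in controls, and the serine synthesis enzyme Psat1 by 0.78 and 0.70 at 30 min. At 240 min 4 and 5 cholesterol synthesis genes were higher (adjusted p = 0.00012 and 4.3e-06, or 0.010 and 0.0035).

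Other lists called between genotypes did not hold with an estimated correlation. Oxidative phosphorylation genes were lower, 15 and 6 of 27 in controls at 30 and 240 min and 7 and 6 in heated cells (adjusted p = 7.2e-05, 0.0027, 0.011 and 0.010, then 0.20, 0.37, 0.46 and 0.45), with a median of 0.04 in the controls at 30 min after median centring. NF-kB and inflammatory genes were higher, 11, 4, 7 and 4 of 17 with 2, 1, 3 and 1 lower in the same order (adjusted p = 0.00067, 0.0024, 0.026 and 0.023, then 0.41, 0.46, 0.60 and 0.60). Immediate early genes were higher in controls, 12 and 4 of 29 with 3 lower in each (adjusted p = 0.017 and 0.033, then 0.20 and 0.26). So were ER chaperones in the 30 min controls (7 of 19, 1 lower; adjusted p = 0.013, then 0.17). Also higher were ribosomal protein genes in the heated cells at 30 min (15 of 45, 1 lower; adjusted p = 0.048, then 0.75), and mitotic genes at 240 min (adjusted p = 0.013 and 0.0093, then 0.20 and 0.18). In the heated cells at 30 min 14 of 28 extracellular matrix genes were higher and 2 lower (adjusted p = 0.00055, then 0.17). At 240 min 2 of 10 chondrocyte markers were lower in controls (adjusted p = 0.020, then 0.26), and erythroid markers were called in heated cells without a single member (adjusted p = 0.049, then 0.47). The HOX genes, chromosome 17 neighbours, DAXX, HIPK and ASK1-JNK pathway, BCL2 family, CCT chaperonin, proteasome, glycolysis, histone, endothelial, adipocyte and hepatocyte lists were not called in these 4 comparisons.

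The genotype effects of both time sets were then compared with each other. Across 13488 genes the control effects correlated at 0.374 and the heated ones at 0.267; these pairs share no arrays, only the reference RNA, and genes are not independent replicates. Of the called genes 241 were higher and 631 lower in the controls of both sets, where independent lists would share 95.08 and 215.8, and 145 were called in opposite directions. Dcn was among the latter, at 1.16 in the 30 min controls and -1.04 at 240 min, as was Hspb8, at -1.32 and 0.41, the second of which lost its call with slide as a block (adjusted p = 0.053). Heat effects at 30 and 240 min correlated at 0.628 in the wildtype and 0.706 in the CHIP null.

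The controls of both time labels differed in 8573 genes in the wildtype, 3768 higher and 4805 lower at 240 min, and in 6563 in the CHIP null, 2568 higher and 3995 lower. In the wildtype Il1rl1 (3.26), Penk (1.77, other probe 0.06), Bst2 (1.56) and the sterol enzyme Idi1 (1.54) were higher at 240 min, and Ncan (-3.65), Marco (-2.92) and Fabp7 (-2.73) were lower. Xist was at least 2.81-fold higher (1.49) and Eif2s3y at least 3.50-fold lower (-1.81) between the same wildtype controls. Between the CHIP null controls Trib3 (1.31), Idi1 (1.03) and the prostaglandin synthase Ptgs2 (0.99) were higher and Slpi (-1.99), the differentiation inhibitor Id1 (-1.68) and Mmp3 (-1.43) lower. Cholesterol synthesis genes were higher in both, 21 and 17 of 22 (adjusted p = 1.5e-12 and 3.9e-13, or 0.00015 for each with an estimated correlation). Of 16 actin and SRF targets 15 and 13 were lower (adjusted p = 8.4e-07 and 5.6e-05, or 0.015 and 0.044). In the wildtype 18 of 23 mitotic genes and 20 of 23 replication genes were also higher (adjusted p = 1.5e-07 and 1.8e-07, or 0.0096 and 0.017). Since each time label is its own scan set, time cannot be told apart from it. The wildtype cultures also differ in Xist and Y-linked RNA, so the same cells are not followed over time.

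The heat effect itself differed between the time labels for 170 genes in the wildtype, 100 with a higher value at 240 min and 70 with a lower one, and for 320 in the CHIP null, 146 and 174. In the wildtype Hspa1a differed by 2.89 ± 0.54 (1.09 to 2.64 by its other probes), Lyz2 by 2.26, Marco by 1.75 and the linker histone H1f4 by -0.80, which lost its call with slide as a block (adjusted p = 0.13). Lyz2 and Marco were already lower in the wildtype controls labelled 240 min (mean log2 ratios of -2.86 and -2.50) than in those labelled 30 min (0.02 and 0.42). In the wildtype the sets also differ in Xist and Y-linked RNA. Mitotic genes had a higher heat effect at 240 min in both genotypes, 10 in the wildtype and 3 in the CHIP null (15 and 13 over the list alone; adjusted p = 2.6e-11 and 1.5e-07, or 0.0019 and 0.0096 with an estimated correlation). With slide as a block the counts were 20 and 18, and with median centring 28 and 8.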

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

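The tests by other splits of the arrays, the test of exchanged genotype labels, the test of sex and the check of the time label over other scalings were chosen only after the results were seen. With slide as a block a heat effect rests on 1 array in one of its arms, so a call kept or lost there may reflect that array. The gene and list differences that come first are here because heat effects of different genotypes or times were tested against each other.

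The heat effect at 30 min differed between the genotypes in 60 genes. The difference (CHIP null minus wildtype) was 1.83 for Marco, 1.19 for Lyz2, 1.11 for Adam8, 0.71 for Pf4, 0.69 for Mpeg1, 0.65 for Selenop, 0.61 for C1qc and 0.50 for Rab6b. It was -0.47 for Cse1l, -0.45 for Hnrnpa3, Twist2 and Egr1, -0.44 for Ednra and -0.33 for Pus10. Marco, Lyz2 and Adam8 were already lower in the CHIP null controls (mean log2 ratios of -1.95, -2.67 and -0.15) than in the wildtype controls (0.42, 0.02 and 1.11). Of these 14 genes only Marco, Lyz2 and Adam8 were called with slide as a block, and Hnrnpa3 turned to 0.10 by another probe. Of 100 splits of the 12 arrays 5 gave at least the 59 genes called among those measured on all arrays, so chance is not excluded. The highest other split gave 465. At 240 min limma called 0 genes (471 at an unadjusted p under 0.05), so splits decide nothing there.

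In the wildtype the heat effect differed between the time labels in 170 genes. The difference (240 minus 30 min) was 2.89 for Hspa1a, 2.26 for Lyz2, 1.75 for Marco, 1.68 for Lyz1, 1.49 for Adam8, 1.0 for Ctss, 0.95 for Csta2 and 0.91 for Rsrp1. It was -0.89 for Dzip3, -0.80 for H1f4 and H1f5, -0.75 for Stard4 (0.18 by another probe), -0.67 for H2ac10, -0.63 for Taok1 and Dnm3os and -0.60 for Suz12. Lyz2 and Marco were already lower in the controls labelled 240 min (mean log2 ratios of -2.86 and -2.50) than in those labelled 30 min (0.02 and 0.42). With slide as a block the named genes with higher values kept their calls and the named genes with lower values did not. The CHIP null had 320 such genes, among them Lyz2 by 1.16 (-0.032 by its other probe), Hnrnph2 by 0.65, Cep55 by 0.59, Mad2l1 by 0.55, Vbp1 by 0.54, Hsp90aa1 by 0.52, and Fgf7 and Sap30 by 0.51. Lower values were -0.91 for Grn, -0.78 for H1f5, -0.77 for Plpp3, -0.69 for Zfp36l1, -0.66 for Wwtr1, -0.64 for Cdkn1c and -0.63 for Stard4 (0.10 by another probe) and Kif5b. There Lyz2, Hnrnph2, Hsp90aa1, H1f5 and Plpp3 kept their calls with slide as a block. Only 1 of 100 splits, the real one, gave as many genes in each genotype (167 against 6 in the highest other, and 294 against 172). That share is under 0.05, but the splits ignore slides and take the arrays as independent. Time label and scan set cannot be told apart, and the wildtype sets also differ in Xist and Y-linked RNA. The CHIP null count is less stable, at 76 to 838 when single arrays were left out and 8 with median centring.

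Several lists had a different heat effect in the genotypes at 30 min. The medians of the difference, with 0.027 for all genes not subtracted, were 0.54 for macrophage markers, 0.27 for erythroid, 0.20 for adipocyte, 0.16 for neuronal and glial and 0.10 for endothelial markers. They were 0.15 for extracellular matrix genes, 0.11 for oxidative phosphorylation genes and 0.10 for ribosomal protein genes and for actin and SRF targets. Lower were -0.12 for NF-kB and inflammatory genes and -0.060 for immediate early genes. Only the macrophage list held with an estimated correlation (adjusted p = 0.0011; 0.20 to 0.63 for the others). With median centring the medians of the ribosomal, matrix, actin and oxidative phosphorylation lists fell below that of all genes, as did the endothelial one with a common slope, the ribosomal and erythroid ones with the Feature Extraction ratio and the ribosomal, oxidative phosphorylation and neuronal ones with Cy5 alone. At 240 min the medians, with -0.0013 for all genes, were 0.16 for epithelial and muscle markers, 0.13 for neuronal and glial, 0.12 for hepatocyte, 0.11 for endothelial and 0.076 for macrophage markers and -0.083 for actin and SRF targets. None of these held with an estimated correlation (adjusted p = 0.20 to 0.52). The medians of macrophage and endothelial markers fell below that of all genes with Cy5 alone and that of hepatocyte markers with a common slope.

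The other comparisons set 3 arrays against 3, and their 10 splits, of which 1 gave as many genes, are too few for a share under 0.05. For the heat effect the real and highest other counts were 1964 and 0 in the wildtype at 30 min, 4245 and 0 at 240 min, 4753 and 39 in the CHIP null at 30 min, and 5263 and 1163 at 240 min. For the genotype they were 4592 and 0 in controls at 30 min, 1762 and 0 at 240 min, 3706 and 7 in heated cells at 30 min, and 1749 and 597 at 240 min. For the time labels they were 8573 and 1 in the wildtype and 6563 and 1 in the CHIP null. The real splits by genotype and by time also part the slides. Of 100 regroupings of all arrays, the real one included, 2 gave as many list calls for the heat family (37, highest other 38) and 2 for the genotype family (75, highest other 75). That share is under 0.05, but the regroupings ignore slides and take the arrays as independent, which the labels do not settle.

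A first pattern is that the value table holds all 24 arrays under the other time label. Were the scanner files the mislabelled side, the signed heat effect on the cytosolic heat shock list should have been lower at 240 than at 30 min. Instead the heat effect on its array medians was higher at 240 min by 0.0972 (SE 0.0461) in the CHIP null and 0.162 (SE 0.0412) in the wildtype. More genes were also called at 240 min. In size, however, the median change of its genes was larger at 30 min. It was -0.0628 at 30 and 0.0513 at 240 min in the wildtype and -0.0903 and 0.0058 in the CHIP null. Over 5 other scalings the difference of array medians was above 0 in 9 of 10 values, and -0.0259 (SE 0.0899) in the wildtype with the Feature Extraction ratio. It reached 0.62 (SE 0.146) in the CHIP null with Cy5 alone, where the median change of the genes was -0.126 at 30 and -0.00692 at 240 min. Although fixed beforehand, this does not decide. In the CHIP null all 5 called more genes at 30 than at 240 min, such as 3861 and 2518 with Cy5 alone, and the expectation assumes that longer exposure brings more change. Which label is right cannot be told apart, and no biological explanation was tested.

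A second pattern is that many genotype differences did not recur between the time sets. Genotype labels exchanged between arrays are argued against by Stub1, whose lowest wildtype ratio lay 1.48 above the highest CHIP null ratio. Embryos of different sex may account for part of the pattern, since Xist was higher by a log2 of 1.80 or more in the CHIP null controls at 30 min, the wildtype being not well above background, opposite to the Y-linked transcripts. At 240 min Xist was measured in both genotypes without such a difference, and the Y-linked transcripts were not well above background in either. That test covers sex-linked transcripts and leaves the other genes open. Litter, culture and a genotype effect that depends on time remain open and untested.

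Another pattern is that 96 cell type markers, macrophage ones included, lay 0.214 (SE 0.0881) above the median of all genes after heat in the CHIP null at 30 min. Differences in ratio slope between arrays may account for it, since with ratios scaled to a common slope the value was 0.0527 (SE 0.0474). With the Cy5 channel alone it was 0.0873 (SE 0.0127), neither within 2 standard errors of 0 nor above the 0.1 set beforehand, so an effect of the reference channel cannot be told apart. A response to heat stays open as untested.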

How the results depend on the processing

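The tests with outlier spots kept, with ratios scaled to a common slope and within the slide that holds both treatments were chosen only after the results were seen. Of 404 other values of the counts, 301 lay within 1.5 times the main count and 103 did not. Of 6841 other values of named genes, 6194 kept their direction and their side of the threshold, 88 changed sign without a call in either fit, 410 kept the direction but lost the call, 31 gained a call and 118 turned. Quantile scaling between arrays of the mean brightness leaves ratios as they are and so tests nothing. For counts that moved and values that turned, the cause was not tested unless stated.

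The value table carries the other time labels, which by construction turns every comparison of times and exchanges the time sets of the rest. Its counts were 2714 and 2808 for heat in the wildtype at 240 min and the CHIP null at 30 min. The genotype difference of the heat effect had 0 and 59 at 30 and 240 min. There were 1166 and 4743 for the genotype in controls and 1161 and 5291 in heated cells. Time in the CHIP null gave 2996, with 102 and 112 for the time difference of the heat effect in the wildtype and CHIP null. Heat lists fell to 17.

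With slide as a block each heat effect sets 1 array against 3, as within slides, and the genotype effects also hang on a lone array. The heat counts were then 449 and 616 in the wildtype and 2675 and 2742 in the CHIP null (449, 616, 2679 and 2742 within slides). The genotype counts were 1631, 467, 1708 and 368 for controls and then heated cells at 30 and 240 min. The genotype differences of the heat effect fell to 10 and rose to 1 (Hspa1a, by the lone heated wildtype array), its time differences fell to 20 and 18, and the heat lists to 20. Median centring gave 619 and 1851 for heat in the wildtype. For the genotype it gave 2866 and 833 in controls and 1539 in heated cells at 30 min, with 5 for the genotype difference of the heat effect at 30 min and 28 and 8 for the time differences. Cy5 alone gave 2273 and 2518 for heat at 240 min in the wildtype and CHIP null, and 1075 and 1085 for the genotype at 240 min in controls and heated cells. It left 92 and 75 for the time differences, and 24 heat and 48 genotype lists. The Feature Extraction ratio gave 2650 and 2830 for heat at 240 min in the wildtype and CHIP null, 3050 for time in the CHIP null, 114 for the time difference there and 20 heat lists. An offset of 10 gave 39 for the genotype difference of the heat effect at 30 min and 102 and 106 for the time differences.

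Array weights gave 6411 for heat in the wildtype at 240 min, 3709 for the genotype in heated cells at 240 min. They gave 143 and 7 for the genotype differences of the heat effect and 1061 and 1452 for its time differences. These weights came from the gene-by-gene estimate, because the default one stopped before it converged; it gave 20 where the former gave 7, and 86 with more iterations. A fit to only the groups compared gave 17 for the genotype difference of the heat effect at 30 min and 311 and 65 for the time differences. The common slope gave 3216 for heat in the wildtype at 30 min, 1163 for the genotype in controls at 240 min and 21 heat lists. Genes well above background on all 24 arrays, fewer by construction, gave 32 for the genotype difference of the heat effect at 30 min and 17 heat lists, and no filter gave 57 heat lists. An estimated correlation left 5 heat and 28 genotype lists, and fry, which does not compare a list with other genes, gave 68 heat lists. The wildtype time count, for which slide was a random block only, stayed within 1.5 times under every alternative run for it (6110 to 11804), as did all counts with outlier spots kept and with every probe on its own.

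Of named gene values that lost a call, 53 did so with slide as a block, 46 with the value table, 42 with median centring, and 31 each with Cy5 alone and the Feature Extraction ratio. Another 19 did so by another probe, 18 with an offset of 10, 17 in a fit to only the groups compared, 14 within slides and 10 with a common slope. Median centring moved the median of all genes to -0.18 in heat in the CHIP null at both times. Only Daxx and Hsf1 below lay under it, and only these were called there (limma adjusted p = 0.0093 and 0.014). At 30 min it turned Cdkn1a (-0.16), Daxx (-0.41), Hsf1 (-0.35), Hspa8 (-0.10), Rpl14 (-0.12), Stub1 (-0.16) and Trp53 (-0.018). At 240 min it turned Cdkn1a (-0.12), Rpl14 (-0.047) and Trp53 (-0.12). Cy5 alone turned Grn in heat in the CHIP null at 30 min (-0.48) and in its time difference (0.50). Another probe turned Trp53 for the genotype in controls at 30 min (0.24). Others were Hnrnpa3 in the genotype difference of the heat effect (0.10), Lyz2 in heat in the CHIP null at 30 min (0.11), Lyz2 (-0.032) and Stard4 (0.10) in the time difference in the CHIP null and Stard4 in that of the wildtype (0.18).

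The value table turned, for time in the wildtype, Bst2 (-1.80), Ddx3y (5.70), Eif2s3y (5.91), Fabp7 (2.74), Idi1 (-1.69), Il1rl1 (-0.79), Marco (4.52), Ncan (3.70), Penk (-2.55) and Xist (-5.18). For time in the CHIP null these were Id1 (1.63), Idi1 (-1.01), Mmp3 (2.20), Ptgs2 (-1.26), Slpi (2.29) and Trib3 (-1.11). For the genotype in controls at 30 min it turned Birc5 (-0.050), Dcn (-1.06), Ddx3y (0.11), Eif2s3y (0.049), Hmox1 (0.17), Hspb8 (0.50), Kif20a (-0.021), Mlc1 (0.032) and Mmp3 (-0.21). Heated cells gave Birc5 (-0.033), Dcn (-0.83), Ddx3y (0.069), Eif2s3y (0.038), Hmox1 (0.14), Hspb8 (0.48), Mlc1 (0.10), Mmp3 (-0.59) and Xist (-0.050). At 240 min it turned Bst2 (0.29 in controls and 0.46 in heated cells), Cnn1 (-0.54 and -0.45), Dcn (1.47 and 1.81), Hspb8 (-1.41 and -1.36) and Isg15 (0.47 and 0.68). The same holds for Lum (2.24 and 2.51), Msln (0.79 and 0.58), Myl4 (0.40 and 0.13), Myl7 (0.071 and 0.071), Penk (1.09 and 1.18) and, in controls, Krt8 (0.17). For heat it turned, in the wildtype, Adam8 (0.21), Ctss (0.23), Lyz1 (0.21), Lyz2 (0.13) and Marco (0.087) at 30 min and Hspb1 (-0.0030) at 240 min. Heat in the CHIP null at 30 min gave Cxcl5 (0.10), Grn (-0.17), Hspa8 (-0.070) and Lyz2 (0.20). In the genotype difference of the heat effect at 30 min it turned Ctss (-0.072), Egr1 (0.020) and Pus10 (0.11). In the time difference of the wildtype it turned Adam8 (-1.83), Csta2 (-2.43), Ctss (-1.90), Dnm3os (1.06), Dzip3 (1.64), H1f4 (1.03), H1f5 (1.60), H2ac10 (0.53), and Hspa1a (-2.83). Further ones were Lyz1 (-2.27), Lyz2 (-2.48), Marco (-2.32), Rsrp1 (-0.93), Stard4 (0.76), Suz12 (0.74) and Taok1 (0.64). In that of the CHIP null it turned Cdkn1c (0.58), Cep55 (-0.98), Fgf7 (-0.71), Grn (0.57), H1f5 (1.31), Hnrnph2 (-0.68), and Hsp90aa1 (-0.62), and likewise Kif5b (0.64), Lyz2 (-1.44), Mad2l1 (-0.70), Plpp3 (0.77), Sap30 (-0.90), Stard4 (0.65), Vbp1 (-0.63), Wwtr1 (0.71) and Zfp36l1 (0.61).

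Leaving out each array in turn gave 1052 to 2000 for heat in the wildtype at 30 min, with 1052 and 1202 without control replicates 1 and 2 and 1097 without heated replicate 3. At 240 min it gave 2681 to 4268, with 2807 and 2681 without heated replicates 2 and 3. For the CHIP null it gave 3580 to 4495 at 30 min and 3062 to 6152 at 240 min, the former without heated replicate 3. The genotype difference of the heat effect at 30 min ran from 16 to 232. It was 26 and 23 without wildtype control replicates 2 and 3, and 23, 21 and 92 without heated wildtype replicates 1, 2 and 3. It was 25 and 16 without CHIP null control replicates 1 and 3, and 232, 17 and 26 without heated CHIP null replicates 1, 2 and 3. At 240 min it ran from 0 to 3, the latter without CHIP null control replicate 3. The genotype counts were 3737 to 4359 and 1283 to 1517 in controls at 30 and 240 min and 3112 to 3319 and 1171 to 2077 in heated cells. The time counts were 7799 to 8209 in the wildtype and 5505 to 6390 in the CHIP null. The time difference of the heat effect in the wildtype was 87 to 248. It was 90 and 96 without the 30 min control replicate 2 and heated replicate 3, and 107, 87 and 110 without the 240 min control replicates 1, 2 and 3. It was 104 and 100 without the heated replicates 2 and 3. For the CHIP null it was 76 to 838, with 191 and 110 without the 30 min control replicates 1 and 3, 506 and 95 without the heated replicates 1 and 2. At 240 min it was 108 without control replicate 2, and 838, 76 and 208 without the heated replicates 1, 2 and 3. Heat lists were 34 to 40 and genotype lists 65 to 78. No called value of a named gene turned when an array was left out, 20 values without a call changed sign, and the most calls lost were 16, without CHIP null control replicate 3 at 30 min.

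The replicate numbers did not pair the samples across all groups: over 84 pairs of same-numbered arrays the deviations from group means correlated at -0.286 to 0.571, and only 20 lay over 0.1. The highest were 0.571 and 0.45, for replicates 1 and 3 of the heated arrays of both genotypes at 240 min, with 0.0891 for replicate 2. Pairing between those groups is not excluded. An array correlated best with its own number in 66 of 168 comparisons with another group of 3 arrays, so not every one did. With replicate number as a block within genotype the heat counts were 2001, 4336, 4827 and 5360. The genotype differences of the heat effect were 84 and 0 and the time differences 156 and 341. A block across all groups gave 38 heat and 76 genotype lists. None of these counts moved by over 1.5 times, but a block within genotype does not cover pairing across genotypes. Signal over background limits transcripts that were dim in Cy5, where 33.7% to 49.6% of probes were well above background: a group in which a transcript was dimmer gives only a bound, and a lack of change there shows nothing.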

Other observations

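The tests of gene length in the genotype and time comparisons were chosen only after the heat result was seen.

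The controls of the time labels also differed in lists not described so far, and each list turned with the value table. ATF4 and CHOP stress genes were higher at 240 min, 13 of 21 in the wildtype with 2 lower and 15 in the CHIP null with 1 lower (adjusted p = 0.00091 and 1.1e-07, or 0.013 and 0.00038 with an estimated correlation). Antioxidant and metallothionein genes were lower in the wildtype, 15 of 19 with 1 higher (adjusted p = 0.00064, or 0.015 with an estimated correlation). All 13 macrophage markers were lower in the wildtype and 12 in the CHIP null (adjusted p = 3.8e-07 and 4.6e-07, but 0.13 for both with an estimated correlation). In the wildtype 14 of 20 interferon-stimulated genes were higher and 4 lower (adjusted p = 0.0032, then 0.17). Over both genotypes, and with the time differences of the heat effect counted together with the controls, 47 of 132 tests of lists across time labels were called. With an estimated correlation 13 held.

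Besides mitotic genes, other lists differed between time labels in their heat effect. Immediate early genes fell further at 240 min in the wildtype, with 7 lower and 1 higher adjusted over the list alone (1 lower over all genes; adjusted p = 1.7e-05, or 0.022 with an estimated correlation). Macrophage markers had a higher heat effect at 240 min there, 12 of 13 adjusted over the list alone and 7 over all genes (adjusted p = 4e-24, or 0.0019). Replication-dependent histones had a lower heat effect at 240 min, 4 in the wildtype and 3 in the CHIP null (8 and 6 over the list alone; adjusted p = 3.2e-05 and 0.00071, but 0.18 and 0.25 with an estimated correlation). These directions also turned with the value table, which exchanges the times.

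A hypothesis is that heat lowered transcripts of long genes more than those of short ones, as might follow from slower transcript elongation. It was set down before the correlations were seen. Across genes, the Spearman correlation of the log2 change with gene length in the RefSeq table (GRCm38.p6) was -0.269 and -0.298 in the wildtype at 30 and 240 min and -0.226 and -0.28 in the CHIP null, so the one nearest 0 was -0.226, below the bound of -0.1. Genes are not independent replicates, and 89.3% of the genes tested had a length. For the genotype the correlations lay between -0.0599 and 0.0157, and for the time labels they were 0.0371 and 0.0732. Elongation, RNA stability and probe position were not tested apart, so the explanation remains open.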
